A study of Bos taurus with 2 samples.

How the data were processed

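Single-cell RNA sequencing was done on mammary gland tissue of Holstein dairy cattle, with 1 library from a lactating adult and 1 library from a newborn. Per the labels' protocols, the tissue was freed of fat, cut, treated with EDTA, digested with hyaluronidase, collagenases and DNase at body temperature, and passed through fine strainers. Dead cells were removed where too few cells were viable, and libraries were built with the V3 chemistry of the 10x Genomics 3' kit. Fat cells, large cells and cells that resist the enzymes can be lost in these steps.

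The deposited values are raw UMI counts per gene and cell barcode, which the authors did not normalise. They were made with Cell Ranger 3.1.0, per the submitters' processing notes. The genome build, the annotation and the settings for calling cells are not given in the sources used here, so no coordinates are given. Gene identifiers and symbols were used as the files pair them, which gave 27270 genes, 19730 of them with a symbol. No deposited barcode had fewer than 500 UMIs.

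Barcodes were kept with at least 300 detected genes and at most 20% of UMIs from the 13 mitochondrially encoded protein genes. Doublets were scored per library with Scrublet as run by scanpy 1.11.5, at an expected rate of 0.8% per 1000 barcodes. Its automatic threshold marked 0% of the cells in both libraries and so did not work. The fallback set for that case was applied: the cells with the highest scores were removed up to the expected rate, which was 12.7% in the adult and 11.0% in the newborn library.

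Each library was clustered on its own, so that no cluster was defined by the stage. Counts were scaled to 10000 per cell and log-transformed, and 2000 highly variable genes, 30 principal components, 15 neighbours and Leiden resolution 1 were used with seed 1. Clusters were named from 20 lists of marker genes. A marker was held by a cluster when it reached 20 CPM (UMI counts scaled to the summed UMIs of the same cells) and 25% of its highest level in any cluster of that library. A cluster took the name of the list of which it held the largest share, with at least 3 markers and 30% of the list. Clusters of at least 100 cells that held 50% or more of the lists of different lineages were clustered again with 1000 genes and 20 components. A cluster stayed unnamed if its 10 genes with the largest fold held more markers of another lineage than of its own, or if they held none of its own and its median UMI count was far below that of its library. Names are written as "like" because no deposited annotation was used. Blood vascular and lymphatic endothelial-like clusters were joined into 1 class, and so were T cell-like and cytotoxic or NK cell-like clusters.

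Within a class, raw UMIs were summed over cells and expressed as CPM, and each gene's ratio of newborn over adult was given an exact conditional binomial interval of 95%. Classes with at least 100 cells in both libraries were compared, which left 3. Genes were counted as different in size at 4-fold or more, with at least 50 CPM and 20 UMIs in the higher library. Genes whose CPM in the class was under 10% of that in another class of the same library were left out, because free RNA could account for them. For each of 33 gene lists, the median log2 ratio was taken over members with at least 20 UMIs (prior count 0.5, at least 5 such members), and placed among 10000 random lists of the same size matched on mean expression in 20 bins. A list was called when its median lay in the top or bottom 2.5%. For shares of cells that depend on depth, every cell was thinned to 1000 UMIs and shallower cells were left out. Shares have exact (Clopper-Pearson) intervals, sums of UMIs have exact Poisson intervals, and a count of 0 is given with the limit that 3 counts allow. With 1 library per stage no test between stages could be made, so no p-value is given.

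The genes named for each compared class were those with the 10 largest ratios in each direction that had a symbol and passed the limits above, leaving out mitochondrially encoded, ribosomal protein and milk protein genes, and the report names part of them. A gene with 0 UMIs in 1 library was ranked against a floor of 3 UMIs. Members of gene lists were named as those with the largest ratio in the direction of the list's median and 1 that went the other way, and genes of epithelium, contraction and each cluster's leading genes were named beside the clusters. The cell filter, doublet rule, clustering, marker and gene lists, comparisons, naming rule for genes and most alternatives were fixed before the data were examined. The thresholds for naming clusters, the splitting of mixed clusters and the joining of classes were set after the data had been seen. So were the stricter guard against free RNA at 50%, the separate comparisons with blood vascular or lymphatic cells of the adult, and the choice of genes named from them.

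The alternatives covered the cell filter, doublet removal, clustering, thinning depth, scaling, the limits on low counts, the guard against free RNA and the size threshold. The comparison was tested on simulated data for the fibroblast-like class, with 27270 genes of which 200 were changed. Both simulated libraries were Poisson counts drawn from 1 shared profile, and the changed genes were chosen among well expressed ones. The simulation therefore checks the computation under counting error only, and cannot show how often animals, handling or libraries alone would give 4-fold differences. Of 100 genes changed 8-fold, 99 passed the 4-fold limit, and of 50 genes changed 16-fold, 50 did. Of 50 genes changed 2-fold and 2403 unchanged genes, 0 passed it. Among the unchanged genes, 95.6% of the intervals held the true ratio, and this share was not computed for the changed genes. Computations used python 3.11.15, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9 and matplotlib 3.10.9.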

Results

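Single cells of the bovine mammary gland were profiled at 2 stages, with 1 library from a lactating adult and 1 from a newborn. The adult library held 15897 barcodes and 85388618 UMIs, with a median of 2723 UMIs and 934 genes per barcode. The newborn library held 13772 barcodes and 65597671 UMIs, with a median of 4581 UMIs and 1358 genes. The median share of mitochondrially encoded UMIs was 4.59% in the adult and 1.3% in the newborn library. The gene and mitochondrial limits removed more adult barcodes, of which 990 had too few genes and 722 too many mitochondrial UMIs, against 46 and 30 in the newborn library. They left 14691 adult and 13710 newborn barcodes, and removal of 1868 and 1511 likely doublets left 12823 (80.7%) and 12199 (88.6%) cells. The study states 24472 cells. The files held 29669 barcodes, of which 28401 passed the gene and mitochondrial limits and 25022 were kept. Each stage is a single library with no replicate check, so a cluster may reflect its library, stage, animal, tissue handling and library cannot be separated, and all intervals and floors cover counting error only.

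The 2 libraries held almost opposite sets of cells. The adult library was dominated by immune cells, at 66.9% (66.1 to 67.7) of kept cells, of which T or NK cell-like clusters made up 54.1% (53.2 to 54.9) of all cells. The newborn library consisted mostly of fibroblast-like cells, which carry collagens and proteoglycans such as COL1A1 and DCN, at 85.5% (84.9 to 86.1) against 1.61% (1.40 to 1.85) in the adult. Endothelial-like cells, which line blood and lymph vessels, were 19.6% (18.9 to 20.3) of adult and 0.853% (0.697 to 1.03) of newborn cells. Epithelial-like cells were 8.94% (8.46 to 9.45) of adult cells, and 0 of 12199 newborn cells were assigned to them, which allows a share of up to 0.0246%. Mast cell-like cells went the other way, at 8.12% (7.64 to 8.62) in the newborn and 3.55% (3.23 to 3.88) in the adult library, although the newborn share was 5.19% with a limit of 500 genes.

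The adult epithelial-like cells formed a luminal class of 719 cells (clusters A8 and A16, numbered by size within the adult library), a milk-secreting class of 408 cells (A12) with a median of 36049.5 UMIs per cell, and a basal or myoepithelial class of 20 cells (A25). A8 was led by LCN2, WFDC2 and SAA3, genes of innate defence, and A12 by milk genes such as CSN2, CSN3 and BTN1A1. Of the 2512 adult endothelial-like cells, 2378 (94.7%) were lymphatic, with LYVE1, RELN and MMRN1 among their leading genes, and 134 were blood vascular. The newborn endothelial-like cluster of 104 cells (N14, N for newborn) carried ACKR1 and SELP of venous vessels beside MMRN1, CCL21 and LYVE1 of lymphatic vessels. Smaller adult classes were neutrophil-like (5.66%), macrophage or monocyte-like (2.19%), B cell-like (0.788%), plasma cell-like (0.507%) and dendritic cell-like cells (0.140%). In the newborn library, T or NK cell-like (0.779%), dendritic cell-like (0.303%), neutrophil-like (0.246%) and macrophage or monocyte-like cells (0.189%) were found. The newborn dendritic cell-like cluster (N17) was mixed, with 60.0% of its own and 58.3% of the T cell markers and CD3E among its leading genes. No name was given to 2.96% of adult and 3.98% of newborn cells. The newborn unnamed cells were 1 cluster of 486 cells with fibroblast markers and a median of 756.5 UMIs. Dissociation and straining can set these shares. Because names were rebuilt from markers and 11 newborn clusters make up the fibroblast-like class against 1 (A17) in the adult, the stages were not matched cluster by cluster.

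**Figure D1:**
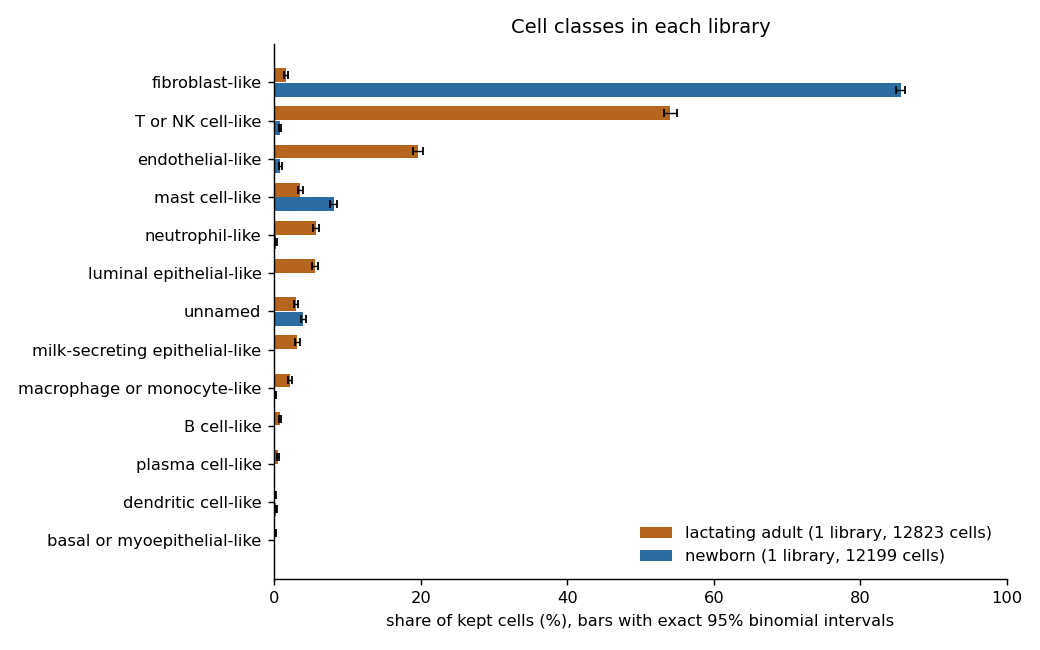
Share of kept cells in percent (horizontal axis) for each class (vertical axis), for the lactating adult library (12823 cells) and the newborn library (12199 cells), with exact binomial intervals of 95% as black bars. Fibroblast-like cells make up 85.5% of the newborn and 1.61% of the adult library, and T or NK cell-like cells 0.779% and 54.1%.

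The title of the series asks about myofibroblasts with epithelial features, so genes of contraction, collagen and epithelium were read in each stromal and epithelial cluster. No cluster of either library was named as myofibroblasts or as pericytes and smooth muscle. The newborn fibroblast-like clusters N10 and N13 came closest, with 71.4% of the myofibroblast markers, most of them matrix genes such as COL1A1 and COL3A1, behind 80.0% and 86.7% of the fibroblast markers. ACTA2, the smooth muscle actin of contractile cells, reached 5024 CPM (4630 to 5441) in the 20 basal or myoepithelial-like cells of the adult (A25). This cluster depends on the processing, since no cell took its name under 4 of the alternatives for filtering and clustering. The 20 cells also held MYH11 at 2044 CPM, KRT17 at 9054 CPM, KRT5 at 3572 CPM and KRT8 at 1102 CPM, which are a muscle myosin and epithelial keratins. Some matrix genes of fibroblasts were nearly missing from them, with 1 UMI of COL1A1 (8.34 CPM) and 0 UMIs of COL3A1 and DCN. The fibroblast marker list as a whole was not, at 240 UMIs (2003 CPM, 1757 to 2273). It stood at 115 CPM in adult T or NK cell-like, 2179 CPM in endothelial-like and 49805 CPM in fibroblast-like cells. Which members carried these UMIs is not given here. POSTN, a matrix protein of activated fibroblasts, stood at 300.4 CPM in the 20 cells. COL17A1, a collagen of epithelial anchoring, was among their leading genes. Adult fibroblast-like cells (A17) held COL1A1 at 3175 CPM and COL3A1 at 3855 CPM with only 5 UMIs of ACTA2 (7.45 CPM) and 4 of TAGLN (5.96 CPM). In the newborn library ACTA2 was counted 27 times over all barcodes (0.412 CPM), and MYH11 reached at most 5.77 CPM in a fibroblast-like cluster (N13, 3 UMIs). The fibroblast-like cluster N4 held some contractile genes beside COL1A1 at 10079 CPM, namely CNN1 at 47.4 CPM (in 8.52% of its cells), OXTR at 33.2 CPM, DES at 31.2 CPM and MYLK at 13.3 CPM, with ACTA2 at 0.324 CPM. N4 did not stand alone in these, as DES stood at 33.5 CPM in N10 and 40.4 CPM in N13, and MYLK at 12.7 and 30.8 CPM. CNN1 stood at 15.6 CPM in N10 and at 4.55 CPM or less in the other newborn fibroblast-like clusters, and POSTN, at 89.3 CPM in N4, reached 93.3 CPM in N12.

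**Figure D2:**
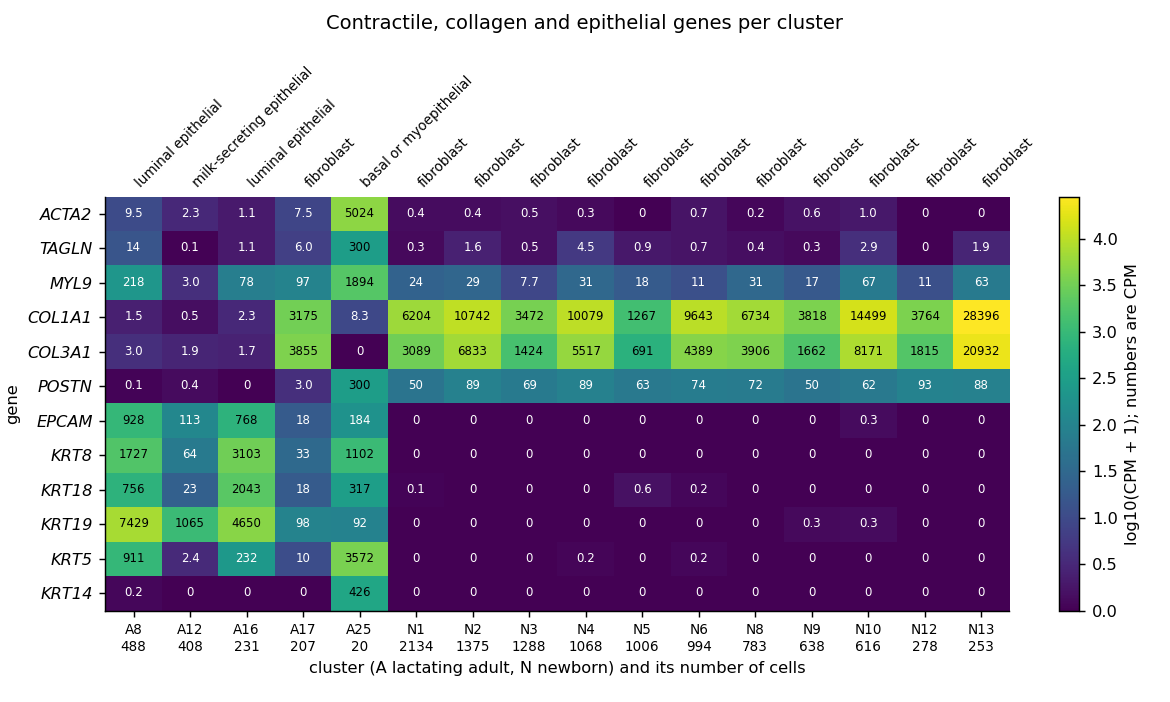
CPM of 12 genes (vertical axis) in each epithelial-like and fibroblast-like cluster (horizontal axis, with its number of cells), coloured by log10(CPM + 1). ACTA2 stands at 5024 CPM in the 20 adult basal or myoepithelial-like cells, where COL3A1 is at 0, and COL1A1 stands at 3175 CPM in the adult fibroblast-like cells, where ACTA2 is at 7.45.

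Epithelial transcripts in adult fibroblast-like cells were near the level in T or NK cell-like cells and were almost missing from the newborn library. With every cell thinned to 1000 UMIs, 15 of 177 adult fibroblast-like cells (8.47%, 4.82 to 13.6) showed at least 2 of 15 epithelial genes, after 30 shallower cells were left out. T or NK cell-like cells of the same library, which should lack these genes, reached 5.92% (5.36 to 6.52) and endothelial-like cells 5.69% (4.76 to 6.74). The level was not alike in the other immune classes, at 3.00% (1.3 to 5.82) in macrophage or monocyte-like and 43.7% (36.8 to 50.8) in neutrophil-like cells. In the latter 520 shallower cells were left out, and which genes of the list gave the share was not resolved. The median depths were 2237 UMIs in fibroblast-like and 2679 in T or NK cell-like cells, and without thinning the shares were 25.6% and 25.5%. The share in adult fibroblast-like cells was therefore not set apart from background, and its source stays open. Of 9922 newborn fibroblast-like cells, 0 met the limit (511 left out), which allows a share of up to 0.0302%, and 2 of 10433 did so without thinning. KRT19, a luminal keratin, stood at 98.3 CPM in adult fibroblast-like cells, 7429 CPM in the luminal cluster A8 and 1065 CPM in the milk-secreting cluster. Free RNA was abundant in the adult library, where CSN2, which encodes beta-casein, was found in 100.0% of barcodes, while the newborn library held 1 UMI of it. EPCAM, KRT8, KRT18 and KRT19 together gave 21 UMIs over all newborn barcodes (0.320 CPM, 0.198 to 0.489) against 2127 CPM in the adult.

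Newborn and adult fibroblast-like cells differed in genes of stress, interferon response and some of inflammation and growth on the newborn side, and in antigen presentation, complement and basement membrane on the adult side. PTX3 (ENSBTAG00000009012), a secreted pattern recognition protein of innate immunity, stood at 18507 CPM in the newborn and 139 CPM in the adult library, a ratio of 134 (109 to 165). The small heat shock protein gene CRYAB (ENSBTAG00000000434) was 54.4-fold (32.4 to 99.5), the interferon-induced IFI27 48.0-fold (33.0 to 72.8), the matrix protease gene ADAMTS4 39.8-fold (24.9 to 68.4) and IFI6 26.7-fold (20.8 to 34.7) higher in the newborn library. IGFBP1 (ENSBTAG00000046768), which binds insulin-like growth factors, was 147-fold higher on 1 adult UMI, so its interval ran from 26.5 to 5826. FOSL1 rested on 1 adult UMI as well, at 34.9-fold (6.25 to 1378), and CX3CL1 on 2, at 28.8-fold (7.97 to 238). CYP26B1, which breaks down retinoic acid, had 0 adult UMIs and was at least 26.5-fold higher against the floor of 3 UMIs, with 21.6 as the lower limit of its interval.

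On the adult side, PRG4 (ENSBTAG00000011932), which encodes the lubricant lubricin, stood at 739 CPM against 8.09 CPM, a ratio of 91.3 (80.0 to 104). The aldo-keto reductase gene AKR1C4 (ENSBTAG00000022564) was 1431-fold (592 to 4511) higher on 5 newborn UMIs, and the peptidase gene KLK7 362-fold (180 to 803) higher on 10. COL8A1, a short-chain collagen, was 176-fold (135 to 232), NPPB, a natriuretic peptide, 125-fold (80.9 to 197), and the T cell attractant CXCL9 285-fold (139 to 642) higher in the adult. TMEM176A and TMEM176B had 0 newborn UMIs and were at least 1334-fold and 1052-fold higher against the floor of 3 UMIs, with 1047 and 817 as the lower limits of their intervals. TMEM59L was 143-fold (106 to 194) and JSP, an MHC class I gene, 88.4-fold (75.8 to 103) higher in the adult. CXCL9 was also a leading gene of an adult macrophage-like cluster of 29 cells (A24).

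**Figure D3:**
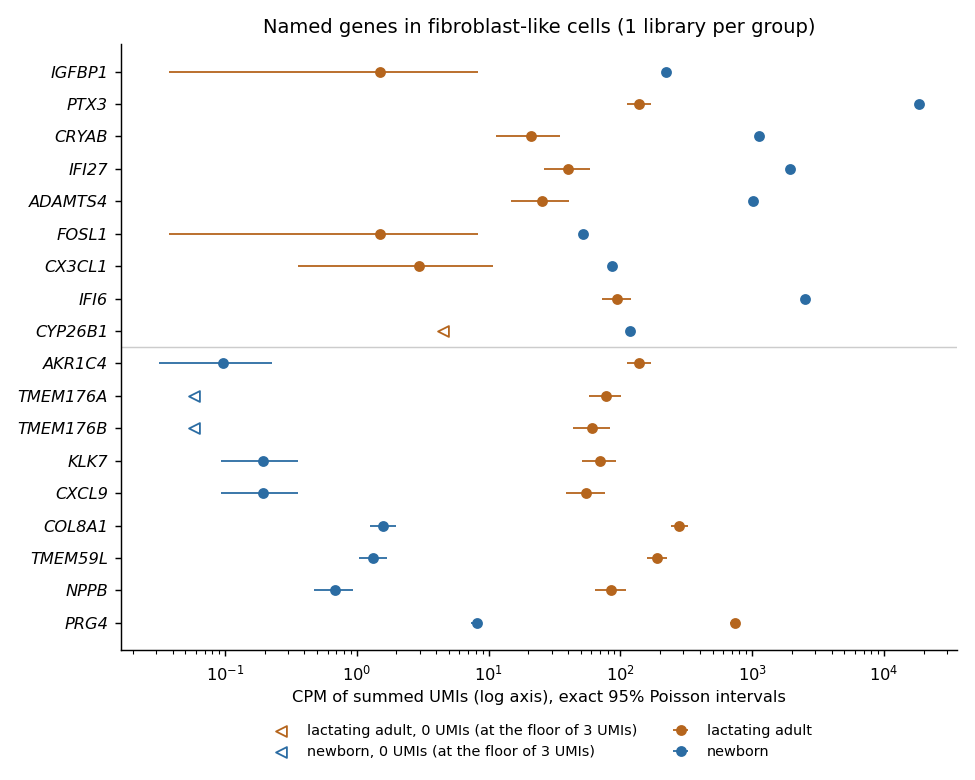
CPM of summed UMIs (log axis) in fibroblast-like cells for the first 9 named genes by ratio in each direction (vertical axis), 1 library per group, with exact Poisson intervals of 95% as lines, and genes with 0 UMIs drawn as open triangles at the floor of 3 UMIs. PTX3 stands at 18507 CPM in the newborn and 139 CPM in the adult library, and PRG4 at 8.09 and 739 CPM.

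Of 3241 genes considered in fibroblast-like cells, 136 were at least 4-fold higher in the newborn and 268 in the adult library. The median log2 ratio of all 4662 genes with enough UMIs was -0.75, a factor of 1.69, and with scaling by the median of ratios the counts were 376 and 102, so 78.7% of these genes in place of 33.7% stood higher in the newborn. List medians are therefore also given relative to the median of all genes. Of 29 lists measured, 7 lay in the top 2.5% of random lists and 7 in the bottom 2.5%. Lists of genes drawn independently would give 1.45 in all. Genes of a list can change together, so this number is not a level of chance for these lists. Over members that passed the guard at 50%, 3 and 3 lists were called.

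Stress genes stood out on the newborn side. Of 13 heat shock genes, which encode chaperones, 11 were at least 2-fold higher in the newborn and 0 in the adult library (median log2 ratio 1.60, relative 2.35), among them HSPA1A at 4924 against 764 CPM and DNAJB1 at 693 against 125 CPM. Of 18 immediate early genes, which respond within minutes to stimuli and to tissue dissociation, 9 were higher and 1 lower (median 1.09, relative 1.84). IER3 stood at 2768 against 487 CPM and BTG2 at 103 against 23.8 CPM, while NR4A1 went the other way at 282 against 724 CPM. Of 22 interferon response genes 14 were higher and 3 lower (median 1.60, relative 2.35, and 1.45 with genes at 0 UMIs set to the floor). ISG15 stood at 796 against 28.3 CPM and IFI6 at 2503 against 93.9 CPM, while CXCL9 went the other way at 0.194 against 55.1 CPM. Of 18 inflammatory genes 7 were higher and 5 lower (median 0.66, relative 1.41, with the floor 0.90, but -0.28 with no doublets removed), with the chemokine gene CCL2 at 9875 against 489 CPM, the acute phase gene SAA3 at 4537 against 182 CPM and CCL5, mostly a T cell product, at 2.27 against 133 CPM. Of 18 genes of hypoxia and glycolysis 4 were higher and 0 lower (median 0.47, relative 1.22, with the floor 0.27), such as VEGFA at 186 against 34.3 CPM, while LDHA stood at 66.5 against 115 CPM. Over the members that passed the guard at 50%, which was added after the data were seen, the median of this last list turned to -0.081. Only 3 interferon and 3 inflammatory genes passed it, too few to measure these lists. The heat shock (1.60) and immediate early (1.41) lists were still called.

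Ribosomal protein genes and some growth genes were higher in the newborn library as well. Of 14 imprinted and fetal growth genes 6 were higher and 3 lower (median 0.33, relative 1.08, with the floor 0.10). PEG10 stood at 107 CPM and MEST at 40.3 CPM with 0 adult UMIs, while CDKN1C, a growth inhibitor, stood at 317 against 1098 CPM. Of 29 ribosomal protein genes 16 were at least 2-fold higher and 0 lower (median 1.03, relative 1.78).

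Immune transcripts were also more abundant in adult fibroblast-like cells, where T cell markers stood at 173 CPM against 2.38 CPM in the newborn ones, so free RNA of immune cells can add to the lists of this paragraph. On the adult side, 8 of 10 genes of MHC class I presentation, which show peptides to T cells, were at least 2-fold higher in the adult library and 0 in the newborn (median -2.49, relative -1.73), with BOLA at 186 against 2098 CPM and PSMB9 at 1.94 against 29.8 CPM. Of 13 complement genes 8 were higher in the adult and 1 in the newborn (median -2.72, relative -1.97), with CFD at 17.6 against 526 CPM and C7 at 15.3 against 221 CPM, while CFB stood at 814 against 218 CPM. Of 11 basement membrane genes 9 were higher in the adult and 0 in the newborn (median -1.69, relative -0.93), with COL18A1 at 22.6 against 508 CPM and LAMA2 at 60.5 against 262 CPM. Of 13 mitochondrially encoded genes 12 were higher in the adult (median -1.91, relative -1.16), as was the median mitochondrial share of that library. Of 6 neutrophil and S100 genes 3 were higher in the adult and 0 in the newborn (median -1.68, relative -0.93, with the floor -1.52), with S100A9 at 0.929 against 10.4 CPM and S100A4 at 122 against 1199 CPM, in a library with 5.66% neutrophil-like cells against 0.246%. Too few members of this list and of the MHC class I list passed the guard at 50% to be measured. All 11 basement membrane genes passed it, with the median unchanged at -1.69. The complement median shrank to -1.14 over 10 members, and the mitochondrially encoded one was -2.03 over 8. These 3 lists were still called.

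Milk protein genes (median -12.59, with the floor -12.49) and luminal keratins (median -5.54) were lower in newborn fibroblast-like cells, beside the free milk and keratin RNA measured in the adult library. Fibrillar collagens and matrix genes were not called, and their direction depended on scaling, with a median of -0.42 that turned to 0.33 relative to all genes. POSTN stood at 68.5 against 2.98 CPM and FBN1 at 619 against 2120.3 CPM. The medians of milk fat synthesis, lactose supply, prolactin, oestrogen, TGF-beta, cell cycle, unfolded protein, nuclear oxidative phosphorylation, adipogenic, regulatory T cell and endothelial activation genes also turned from negative to positive, and none of these lists was called. Smooth muscle contraction (-1.46), endothelial angiogenesis (-0.99) and naive T cell genes (-1.36) were not called either and kept their sign.

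**Figure D4:**
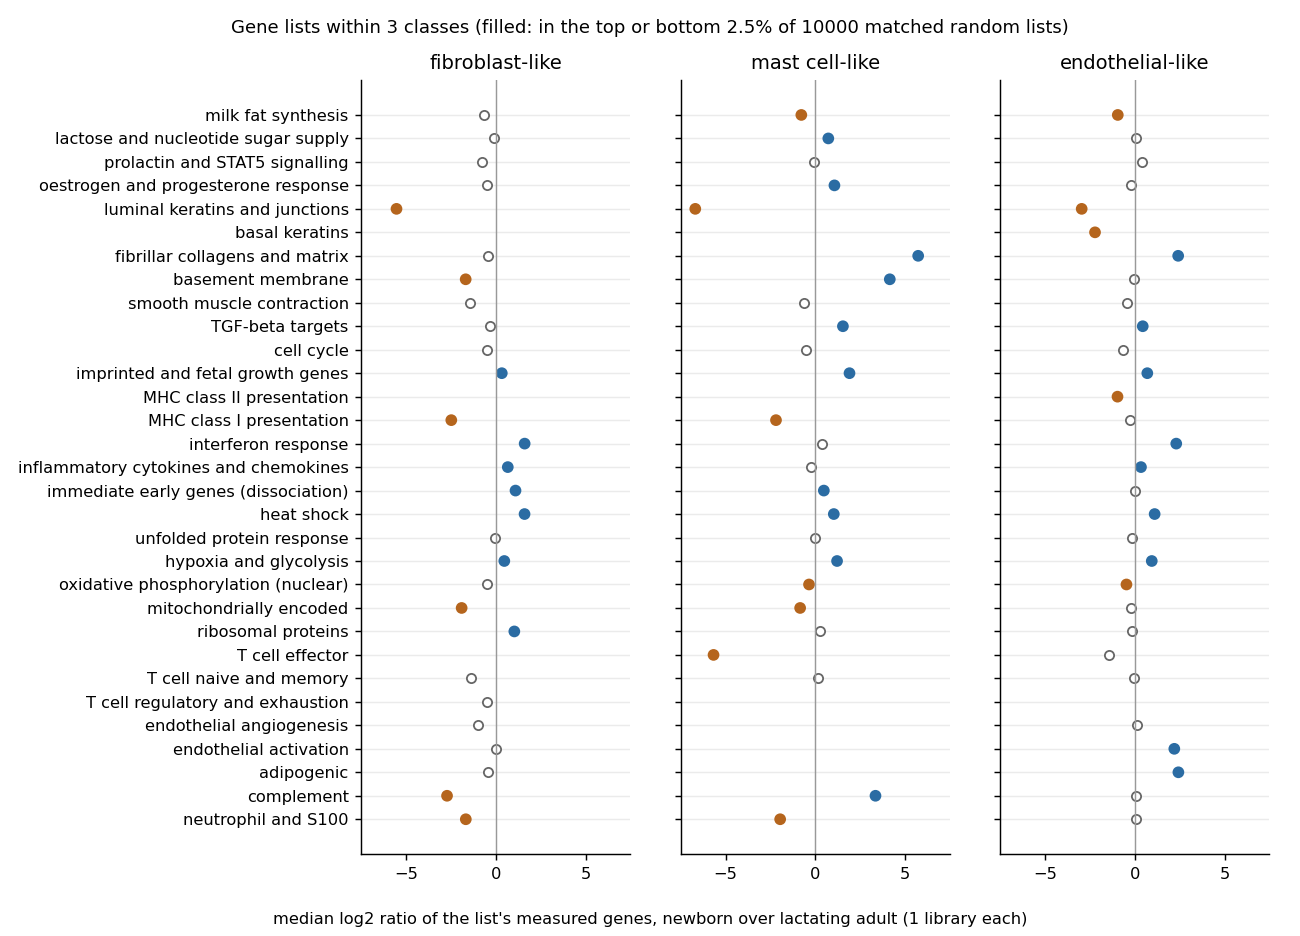
Median log2 ratio of newborn over lactating adult (horizontal axis, 1 library each) for each gene list (vertical axis) in fibroblast-like, mast cell-like and endothelial-like cells, with filled points for lists in the top or bottom 2.5% of 10000 matched random lists and open points for the others. Heat shock genes stand at 1.60 in fibroblast-like and 1.03 in mast cell-like cells. The milk protein list is left out of the plot, and in fibroblast-like cells the median of all genes is -0.75, so that points between this value and 0, such as the fibrillar collagens, change side with scaling.

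Endothelial-like cells of the newborn held more transcripts of some adhesion and inflammatory genes, such as SELE, than those of the adult, which were mostly lymphatic. SELE (ENSBTAG00000007307), the E-selectin that captures leukocytes, was 366-fold (188 to 816) higher in the newborn, at 232 against 0.632 CPM. ACKR1, a chemokine receptor of venules, stood at 2411 against 119 CPM, the neutrophil growth factor gene CSF3 at 2500 against 122 CPM and HSPA1A at 9722 against 1451 CPM. CSF3 was among the leading genes of the adult blood vascular cluster A18, and no value against blood vascular cells alone is given for it. On the adult side the sterol synthesis genes CYP51A1 (ENSBTAG00000001992), HMGCS1, MVK, IDI1, MSMO1 and FDPS were 25.6-fold (10.0 to 94.2), 14.7-fold (8.74 to 26.9), 7.57-fold (3.47 to 20.7), 6.52-fold (3.94 to 11.7), 6.49-fold (4.88 to 8.85) and 5.90-fold (3.51 to 10.8) higher. Genes of fibroblasts were among those with the largest ratios on the newborn side, such as COL1A2 (158-fold, 120 to 211), COL3A1 (112-fold, 84.1 to 151), the imprinted DLK1 (74.6-fold, 48.4 to 119) and DCN (67.9-fold, 58.7 to 78.8), beside 39.3 UMIs of fibroblast markers per newborn endothelial-like cell and 12.4 per adult one. The vasoconstrictor gene EDN1 was 6.04-fold (3.05 to 14.0) and the growth factor gene PDGFB 5.28-fold (2.55 to 13.2) higher in the adult.

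The makeup of the class set part of these values. Against the 134 adult blood vascular cells alone, SELE was still 25.2-fold (12.9 to 56.0) higher in the newborn and CCL2 9.53-fold (6.93 to 13.4), while ACKR1 was 1.40-fold (1.31 to 1.5) higher. SELP stood at 1272 against 3949 CPM and IL6 at 4428 against 13287 CPM. The sterol gene MSMO1 then had a ratio of 0.939 (0.634 to 1.38) and MVK was still 4.41-fold (1.85 to 12.8) higher in the adult, as was EDN1 at 38.5-fold (19.4 to 89.8) while the interval of PDGFB (2.15-fold, 0.879 to 5.98) included 1. The medians of the lists of endothelial activation, inflammatory genes and TGF-beta targets turned from 2.20, 0.34 and 0.44 to -1.59, -0.68 and -0.27. Against the adult lymphatic cells alone the activation median was 5.25 and MSMO1 was 6.90-fold (5.18 to 9.39) and EDN1 3.64-fold (1.83 to 8.47) higher in the adult. The newborn cluster N14 held 100% of the blood vascular and 87.5% of the lymphatic markers and was not split. Neither comparison therefore sets like against like, and the newborn makeup can add to the changes of sign.

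Of 3115 genes considered, 97 were at least 4-fold higher in the newborn and 23 in the adult, and the median log2 ratio of all genes was 0.02. Of 31 lists measured, 9 lay in the top and 6 in the bottom 2.5%, where lists of genes drawn independently would give 1.55 in all. These numbers were 4 and 2 over members that passed the guard at 50%, and 5 and 10 with adult blood vascular cells only. Of 20 interferon response genes 14 were at least 2-fold higher in the newborn and 2 in the adult (median 2.30), with MX2 at 42.9 against 1.19 CPM. Of 13 heat shock genes 7 were higher and 0 lower (1.08 relative to all genes), of 18 genes of hypoxia and glycolysis 9 and 0 (0.94), and of 9 endothelial activation genes 8 and 0 (2.20). Imprinted genes (0.69, 5 higher and 0 lower) and adipogenic genes (2.42, 4 and 1) were also called on the newborn side. So were inflammatory genes (0.34, with the floor 0.68) and TGF-beta targets (0.44, with the floor 0.67), although their members went both ways, with 7 higher and 6 lower and with 2 higher and 4 lower. Fibrillar collagens were called too (2.41, 13 of 17 higher). The fibroblast RNA given above can add to the collagen, imprinted and adipogenic lists, the last 2 of which hold DLK1. Only 4 of the 20 interferon response genes passed the guard at 50%, too few to measure that list, so free RNA can add to it as well. Called on the adult side were MHC class II presentation (-0.97), nuclear oxidative phosphorylation (-0.47) and milk fat synthesis (-0.95, with the floor -0.50). Of the 5 measured MHC class II genes 0 passed the guard at 50%, so free RNA can add to this list. It was called against adult blood vascular cells only (-2.60) but not against lymphatic cells only (-0.59). Beside the free RNA of the adult library, milk proteins (-5.78), luminal keratins (-2.97, with the floor -2.16) and basal keratins (-2.22, with the floor -1.11) were called too. Immediate early genes (-0.01), cell cycle genes (-0.64), angiogenesis genes (0.14) and the other 13 measured lists were not called.

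Mast cell-like cells (A10 in the adult, N7 in the newborn) carried genes of glycolysis and stress at higher levels in the newborn library. Of 16 genes of hypoxia and glycolysis, 11 were at least 2-fold higher in the newborn and 0 in the adult (median log2 ratio 1.21), with TPI1 at 899 against 326 CPM, PGK1 at 692 against 255 CPM and LDHA at 698 against 264 CPM. Of 13 heat shock genes 7 were higher and 0 lower (1.03), with HSPA1A at 1242 against 383 CPM. Of 16 immediate early genes 3 were higher and 1 lower (0.47). IDI1 (ENSBTAG00000004075), which makes an isoprenoid precursor of sterols, was 35.5-fold (22.8 to 58.6) higher in the adult. There 7 of 8 MHC class I genes were higher as well (-2.20), with PSMB9 at 11.2 against 105 CPM. Of these 8 genes 0 passed the stricter guard against free RNA, so free RNA of other cells can add to this list.

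Many of the most different genes of this class were abundant in other classes. IGFBP3 was 687-fold (123 to 27163) higher in the newborn on 1 adult UMI, PTX3 444-fold (234 to 972), and COL1A2 437-fold (121 to 3611) on 2. Newborn mast cell-like cells held 6.33 UMIs of fibroblast markers each, against 0.202 in the adult. The fibrillar collagen (5.73, 15 of 15 higher), basement membrane (4.15), complement (3.35, with the floor 2.68), imprinted (1.90), TGF-beta (1.53, but -0.22 with more doublets removed), oestrogen response (1.06) and lactose supply (0.72, but a mean of -1.01) lists were called on the newborn side beside this value. CD3E, a subunit of the T cell receptor complex, was 361-fold (64.3 to 14307) higher in the adult on 1 newborn UMI, and CCL5 24.8-fold (15.5 to 42.4). Adult mast cell-like cells held 1.68 UMIs of T cell markers each, against 0.636 in the newborn, beside a T cell effector list at -5.68 (with the floor -3.69). As CPM, the scale of the ratios, the T cell markers stood closer, at 710 in the adult against 469 in the newborn. Newborn fibroblast-like cells held only 0.0118 UMIs of these markers each, so the count in mast cell-like cells may not measure free RNA alone. Milk proteins (-10.59, with the floor -8.06), luminal keratins (-6.70, with the floor -4.64), milk fat synthesis (-0.78), neutrophil and S100 genes (-1.96), mitochondrially encoded genes (-0.85) and nuclear oxidative phosphorylation (-0.36) were also called on the adult side.

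Of 2318 genes considered in mast cell-like cells, 121 were at least 4-fold higher in the newborn and 76 in the adult, with a median log2 ratio of all genes of -0.13. Of 26 lists measured, 10 lay in the top and 8 in the bottom 2.5%, where lists of genes drawn independently would give 1.3 in all. No called list changed sign with scaling by the median of ratios. With the guard against free RNA at 50% the counts of genes were 30 and 41, and over the members that passed it only 2 lists lay in the top and 1 in the bottom 2.5%. Interferon response (0.36), inflammatory (-0.27) and cell cycle genes (-0.52) and the other 5 lists were not called.

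Few fibroblast-like cells showed genes of cell division in either library. After thinning to 1000 UMIs, 28 of 9922 newborn cells (0.282%, 0.188 to 0.408) and 1 of 177 adult cells (0.565%, 0.0143 to 3.11) had at least 3 of 25 cell cycle genes, and without thinning the shares were 10.8% and 6.28%. T or NK cell-like cells reached 7.69% (3.15 to 15.2; 7 of 91) in the newborn and 3.03% (2.63 to 3.48) in the adult, where cluster A19 of 91 cells was led by MKI67 and TOP2A, genes of dividing cells. Mast cell-like cells reached 1.11% (0.448 to 2.28) in the newborn and 1.61% (0.649 to 3.29) in the adult. At this depth no difference was detectable in fibroblast-like or mast cell-like cells.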

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

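The tests of free RNA and the comparison of epithelial RNA between cell classes were chosen after their values had been seen, and the test of doublets was planned, although its reading was changed to use the interval after the value had been seen.

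Basement membrane and complement genes stood on opposite sides in 2 cell classes, which is what marked them for a closer look, and the difference between the classes was not tested. The median log2 ratio of newborn over adult for basement membrane genes was 4.15 in mast cell-like and -1.69 in fibroblast-like cells, a difference of 5.83. For complement genes it was 3.35 and -2.72, a difference of 6.07. COL1A2, a fibroblast collagen, was 437-fold (121 to 3611) higher in the newborn mast cell-like cells, so these values were weighed together with other genes of 1 cell type counted in cells of another.

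Free fibroblast RNA in the newborn library may account for part of the mast cell-like values. Newborn mast cell-like cells held 0.75 (0.697 to 0.808) times as many UMIs of fibroblast markers per cell as the T or NK cell-like cells of that library, or 6.33 against 8.44. The level was not alike in all newborn classes, at 5.43 per dendritic, 12.6 per neutrophil, 39.3 per endothelial and 94.3 per macrophage or monocyte-like cell, and as CPM it was 4668 in mast cell-like and 1759 in T or NK cell-like cells, so the reading rests on 1 pair of classes and on the level per cell. For epithelial genes in adult fibroblast-like cells free RNA may account for the values, since their summed CPM was 0.951 (0.834 to 1.08) times that in T or NK cell-like cells. Doublets of adult fibroblasts and epithelial cells stay open, as the share of cells with epithelial genes without doublet removal was 0.876 (0.422 to 1.85) times that with it. A difference between the stages in mast cells or fibroblasts themselves stays open as well and was not tested.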

How the results depend on the processing

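The free-RNA guard at 50%, the adult blood vascular or lymphatic cells alone and the removal of newborn clusters with few UMIs were chosen after the data had been seen.

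Of the alternatives' values for 26 main results, 199 stayed within the interval of the value reported, or within 1.5 times for counts of genes, and 89 did not. For single genes 609 did and 111 did not. For gene lists 692 values had the same call or lack of one, 28 gained a call, 30 lost it and 7 values of called lists changed sign. Lists that were not called also changed sign with scaling, as given for fibroblast-like cells, and are not among these 7. Where no reason is given, the cause was not tested. Among shares of adult cells, T or NK cell-like cells (54.1%) were 52.2% with at least 200 genes and at most 10% mitochondrial UMIs, 55.1% with at least 500 genes, 51.8% with no doublets removed and 55.5% with 2 times the expected rate removed. Endothelial-like cells (19.6%) were 20.8% with at least 200 genes and at most 10% mitochondrial UMIs and 18.8% with at least 200 genes and no mitochondrial limit, and fibroblast-like cells (1.61%) were 1.88% and 2.05% there and 2.06% with no doublets removed. Epithelial-like cells (8.94%) were 9.67% with at least 500 genes, 9.48% with no mitochondrial limit and 7.03% with 2 times the rate removed. Newborn fibroblast-like cells (85.5%) were 78.4% with at least 200 genes and at most 10% mitochondrial UMIs, 80.5% with at least 500 genes, 75.8% with no doublets removed, 76.1% at Leiden resolution 0.5, 67.8% at resolution 2.0, 76.4% with 1000 highly variable genes and 83.3% with both libraries clustered together. Newborn mast cell-like cells (8.12%) were 5.19% with at least 500 genes, 8.83% with no doublets removed and 8.91% with 2 times the rate removed.

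Shares of cells with several genes of a list depend on the number of genes required by construction, and on depth in most cases. Adult fibroblast-like cells with epithelial genes (8.47%) were 2.42% when thinned to 500 UMIs, 15.9% at 2000 UMIs, 25.6% with no thinning, 35.0% for at least 1 gene and 2.26% for at least 3 genes, and newborn ones (0) were 0.736% for at least 1 gene. Cycling adult fibroblast-like cells (0.565%) were 0 when thinned to 500 UMIs, 0 when thinned to 2000 UMIs, 4.52% for at least 2 genes and 0 for at least 5 genes. Newborn ones (0.282%) were 0.0383%, 1.47%, 3.52% and 0 in the same order.

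Counts of genes at least 4-fold apart are given as newborn and adult. In endothelial-like cells (97 and 23) they were 306 and 218 at 2-fold, 57 and 7 at 8-fold, 32 and 3 at 200 CPM, and 175 and 72 with adult blood vascular cells only. The adult count alone moved to 66 at 20 CPM, 37 with totals without milk protein, mitochondrial and ribosomal genes, 52 with the mean CPM per cell and 38 with no guard, and the newborn count to 44 with the free-RNA guard at 50%. In fibroblast-like cells (136 and 268) they were 75 and 167 both with at least 200 genes and at most 10% mitochondrial UMIs and with no doublets removed, 376 and 102 with the median of ratios, 63 and 62 at 200 CPM, 424 and 1032 at 2-fold and 51 and 69 at 8-fold, and the adult count was 443 at 20 CPM. In mast cell-like cells (121 and 76) they were 240 and 121 with no doublets removed, 223 and 168 at 20 CPM, 42 and 26 at 200 CPM, 295 and 280 at 2-fold and 30 and 41 with the guard at 50%. The newborn count moved to 203 with at least 200 genes and at most 10% mitochondrial UMIs, 223 with at least 500 genes and 80 with 2 times the rate removed, and the adult count to 37 at 8-fold. The fold, CPM and guard limits change these counts by construction.

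Lists in the top and bottom 2.5% of the endothelial-like class (9 and 6) numbered 5 and 10 with adult blood vascular cells only, and 4 and 2 over members passing the free-RNA guard at 50%, which leaves fewer genes. In the fibroblast-like class (7 and 7) they numbered 3 and 3 over members passing that guard at 50%, and the bottom lists 12 with no doublets removed and 11 with at least 5 UMIs. In the mast cell-like class (10 and 8) they numbered 2 and 1 over members passing the free-RNA guard at 50% and 6 and 4 with at least 100 UMIs, and the bottom lists 5 with 2 times the rate removed. With adult blood vascular cells only, the endothelial medians changed sign for TGF-beta targets (-0.27), inflammatory genes (-0.68) and endothelial activation (-1.59). In fibroblast-like cells they changed sign for inflammatory genes (-0.28, no doublets removed) and hypoxia and glycolysis (-0.081, members passing the free-RNA guard at 50%), and in mast cell-like cells for TGF-beta targets (-0.22, 2 times the rate removed) and lactose supply (-1.01, mean in place of the median). Heat shock genes stayed in the top 2.5% with the guard at 50%, at 1.60 in fibroblast-like, 1.14 in endothelial-like and 0.61 in mast cell-like cells. No cell was named basal or myoepithelial-like with either limit of 200 genes, with 1000 highly variable genes or with both libraries clustered together, so its genes have no values there. The 177 adult fibroblast-like cells deep enough for thinning limit what can be said of small shares, since a count of 0 allows up to 1.69%.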

Other observations

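Among the tests in this part, that of handling on every cell type and that of the level of the genes in other cells were planned, and the other tests, among them that of free RNA scaled by markers, and the genes named under the stricter guard were chosen after the results were seen.

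Several genes of sterol synthesis were among those with the largest ratios on the adult side in mast cell-like and endothelial-like cells, which was read from single genes, as no sterol list was measured. In mast cell-like cells, with the free-RNA guard at 50%, SQLE was 19.9-fold (13.3 to 31.1), MSMO1 18.2-fold (12.7 to 26.8) and INSIG1, a sterol-sensing regulator, 16.3-fold (13.1 to 20.5) higher in the adult. In endothelial-like cells HMGCS1 was 14.7-fold (8.74 to 26.9) higher in the adult, most of whose cells were lymphatic. Against adult blood vascular cells only, CYP51A1 (4.83-fold, 1.68 to 19), MVK (4.41-fold, 1.85 to 12.8) and FDPS (2.45-fold, 1.33 to 4.82) were still higher in the adult. The intervals of HMGCS1 (1.79-fold, 0.938 to 3.60), IDI1 (1.57-fold, 0.831 to 3.12) and MSMO1 (1.07-fold, 0.726 to 1.58) then included 1. FCER1A, a chain of the IgE receptor, was 15.1-fold (11 to 21.2) higher in adult mast cell-like cells. The newborn mast cell-like cells held more of the cytokine genes CSF2, at 507 against 13.9 CPM (36.4-fold, 21.9 to 65.4), and IL13, at 310 against 20.4 CPM (15.1-fold, 9.87 to 24.4).

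An unnamed adult cluster of 367 cells (A13) was led by CHGA, IL13, PTGDR2 and IL1RL1 and held TRAT1 and IL7R of the T cell markers. The newborn cluster N20 of 20 cells, named T cell-like, also had CHGA, GATA3 and CYSLTR2 among its leading genes. Adult neutrophil-like cells stood apart from other immune classes in genes of the epithelial list. Of 206 cells 90 (43.7%, 36.8 to 50.8) showed at least 2 of them at 1000 UMIs, after 520 shallower cells were left out. Which genes of the list gave this share was not resolved.

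Epithelial transcripts such as EPCAM and KRT8 were almost missing from the newborn library. Removal of epithelial cells by the cell filter or with the doublets is argued against by 0.320 CPM of EPCAM, KRT8, KRT18 and KRT19 over all newborn barcodes, before any filter. An annotation or counting that misses these genes is argued against by 2127 CPM of the same genes in the adult library. Epithelial cells lost or not sampled before capture could account for the pattern and cannot be told apart from a gland with few epithelial cells at birth, because the largest number of newborn cells in an epithelial-named cluster was 0 under every setting run and the library holds 1 piece of tissue.

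The lists of immediate early and inflammatory genes had medians on the newborn side in fibroblast-like cells, with 9 of 18 and 7 of 18 members at least 2-fold higher and 1 and 5 lower, and the inflammatory median turned to -0.28 with no doublets removed. Handling of the newborn tissue or its dissociation, acting on every cell type, stays open. The immediate early list lay in the top 2.5% in 1 of the 2 other classes, the mast cell-like one. In that class 13 members passed the stricter guard against free RNA. Over these the median was 0.10 in place of 0.47, and the list was not called. Handling stress, read from the heat shock list, may contribute, as that list lay in the top 2.5% in 2 of the 2 other classes. For free RNA of other cells the planned test did not decide, as these genes were up to 1.21 times as high (median) in another newborn class. RNA of the other newborn classes, scaled by their own markers, could supply only 0.592% of their level (median), which argues against it for most of them. It could supply CCL3, CCL4, CCL5 and IL1B in full, and 37.6% of CSF2, 29.1% of CSF3 and 10.9% of IL1A. A difference of stage cannot be told apart from handling with 1 library per stage and stays open as untested.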
